A study of Homo sapiens with 12 samples.

How the data were processed

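The deposited file is a table of counts per gene, which per the submitters' processing notes came from reads handled with Trim Galore 0.6.0, cutadapt 1.15, FastQC and STAR 2.7.0f. The notes also name DESeq2, without its role. The counts are called corrected in the deposited table, without saying for what, and the counting program, genome build, annotation and strand were not given. Per the labels' protocols, barcoded cDNA was made from total RNA by MARS-seq and sequenced on a NextSeq500.

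The table held 28278 genes in 11 libraries, and 13188 genes were at 0 in every library. Library totals ran from 1118710 to 3107871, so that 3 counts are 0.965 CPM in the deepest and 2.68 CPM in the shallowest library. The series lists 12 samples, and replicate 3 of the EZH2 mutant had no column, so it was not analysed here. No column belonged to no sample. Columns marked DM were taken as the double mutant. No genes encoded by the mitochondrial genome were in the table.

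Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups and a minimum count of 10, which left 8813. Libraries were scaled by TMM factors, dispersions were estimated over all 11 libraries, and a robust quasi-likelihood model with 1 term per line was fitted. The comparisons were each mutant line against wild type, the double mutant against each single mutant, and the interaction of the 2 mutations. P-values were adjusted by Benjamini-Hochberg within each comparison, and 0.05 was the threshold. P-values measure only the spread between these samples, because nothing in the labels says that replicates were separate cultures.

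Gene lists were written before the data were examined, 33 lists with 1029 entries, of which 1011 were found and 1 under another symbol. Lists with at least 5 tested genes were tested by camera in limma 3.58.1 with a preset correlation of 0.01, again with an estimated correlation, and by fry. Members were also adjusted over the list alone. The comparisons, test, threshold, scaling, filter and most of the alternatives were chosen before the data were examined.

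Genes were named by a rule fixed before the data were examined. It takes EZH2 and KMT2D, then for each pair of lines the 8 genes with the largest log2 fold change each way among those called, with a mean of at least 10 CPM over the libraries and no overlap between the libraries of the groups. For the interaction it takes 5 each way, and for each list described up to 4 members with the smallest adjusted p. Genes without a gene name and Y-linked genes were passed over. The rule was written for 3 libraries of the EZH2 mutant and applied to the 2 in the table. Genes named outside it, and the genes shown per library, were chosen after their values were seen. Where a group had 3 or fewer counts, the fold change was taken from summed counts with a 95% interval, or as a floor with 3 counts in place of 0. No such interval was computed for the interaction, where fitted values are given. Log2 CPM used a prior count of 2.

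Chromosome arms with at least 30 tested genes were compared by median, and genes along chromosome 19 were taken in blocks of 25. Gene places and the GC content of the last 500 bases came from the reference tables supplied with the data. Overlap of the single mutants was set beside 20 simulations of unchanged groups that share wild-type libraries. All 11 libraries, wild type included, were drawn anew there, each gene independently. The spread of effect correlations and slopes was taken by a jackknife over the 11 libraries.

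Alternatives chosen at that time were RLE and upper-quartile factors, no filter (15090 genes), a strict filter (7129 genes), DESeq2 1.42.0, limma-voom, only the groups compared, a replicate block, and leaving out each library. For the correlations of effects they also held a run over genes of at least 10 CPM. Added after the data were seen were removal of a GC trend, removal of GC and abundance trends with splines of 5 degrees of freedom, leaving out the long arm of chromosome 19, and thinning to equal depth. Only the groups compared was not run for the interaction.

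A self-test planted changes in 100 genes per size. At 2-fold, 67% were recovered between EZH2 mutant and wild type and 83% between KMT2D mutant and wild type, and at 1.5-fold 13% and 39%. Tables were prepared and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.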

Results

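RNA from 4 lines of OCI-Ly7, a cell line grown from a human diffuse large B-cell lymphoma, was counted by MARS-seq, in which barcoded cDNA is sequenced from the 3′ ends of transcripts. The wild-type line was compared with a line carrying the EZH2 Y646N gain-of-function mutation, a line without KMT2D and a double mutant with both changes. EZH2 is the enzyme of Polycomb repressive complex 2 that methylates histone H3 at lysine 27, and KMT2D is a histone H3 lysine 4 methyltransferase that acts at enhancers. Wild type, KMT2D mutant and double mutant had 3 libraries each, and the EZH2 mutant had 2, because the deposited table has no column for its replicate 3. Total counts per library ran from 1118710 to 3107871. In wild type they were 1748860, 2801302 and 2460277, and in the EZH2 mutant 1118710 and 2183775. The KMT2D mutant libraries held 3107871, 1392983 and 2463619 counts, and the double mutant libraries 2165911, 1418465 and 1705894. Of 28278 genes in the table, 8813 had enough counts to be tested.

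The first principal component held 52.9% of the variance, with the 6 wild-type and KMT2D mutant libraries between -44.9 and -9.53 and the 5 libraries with mutant EZH2 between 20.8 and 61.3. EZH2 mutant replicate 1, the shallowest library, lay farthest out, at 61.3 on the first component and 39.6 on the second. Correlations of log2 CPM between libraries of one line were 0.960 to 0.983, and those between EZH2 mutant and double mutant libraries, 0.932 to 0.971, overlapped that range. Markers of other cell types were summed in each line, as CPM of the library total. The myeloid sum was 27.6 ± 6.85 (SD, n = 3) in wild type and 17.2 ± 0.295 (n = 2) in the EZH2 mutant. It was 14.5 ± 3.30 in the KMT2D mutant and 7.12 ± 0.679 in the double mutant (n = 3 each). The fibroblast and epithelial sum was 5.49 ± 0.755, 0.676 ± 0.308, 6.23 ± 2.30 and 3.78 ± 1.61 in the same order. The summed level of the T and NK cell markers was 343 ± 43.7 CPM of the library total (SD, n = 3) in wild type and 259 ± 14.8 (n = 2) in the EZH2 mutant. It was 360 ± 36.3 in the KMT2D mutant and 289 ± 8.96 in the double mutant (n = 3 each). Most of it came from LCK, a kinase of lymphocytes, at 240.2 normalised CPM in wild type and 216 in the EZH2 mutant. Of the tested markers, the interleukin 7 receptor gene IL7R fell in the EZH2 mutant (log2 -1.97) and in the double mutant (log2 -1.63). The myeloid gene AIF1 fell in the EZH2 mutant (log2 -1.35), the KMT2D mutant (log2 -1.10) and the double mutant (log2 -2.97). The smooth muscle actin gene ACTA2 fell in the EZH2 mutant, with 0 counts against 33 in wild type, a call lost without EZH2 mutant replicate 2. PRF1, which encodes perforin, rose in the KMT2D mutant (log2 1.49) and was 6.58-fold lower in the double mutant on 2 counts against 19 (95% interval 1.59 to 58.3). Intervals and floors cover counting error only.

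**Figure D1:**
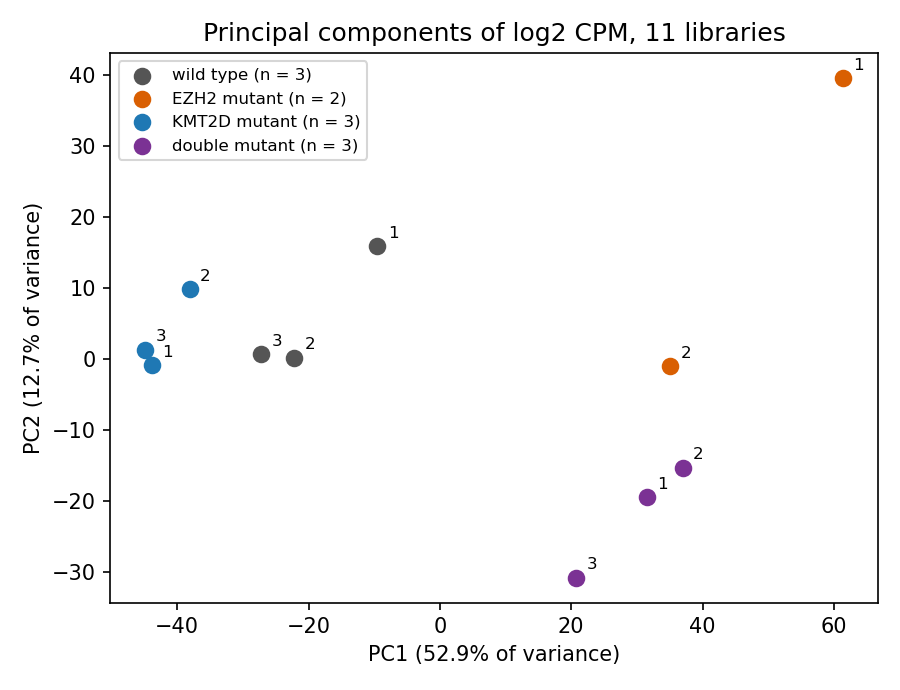
Principal components of log2 CPM of the 11 libraries; points are libraries, coloured by line and numbered by replicate, and the axes give each component's score with its share of the variance. Wild-type and KMT2D mutant libraries lie below -9.5 on the first component, and EZH2 mutant and double mutant libraries above 20.

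The targeted genes were read in every library first. EZH2, on the minus strand of chromosome 7 from 148807383 to 148884321 of GRCh38 in GENCODE 29 (ENSG00000106462.10), stood at 76.9 ± 7.52 normalised CPM (SD, n = 3) in wild type, 64.6 ± 14.6 (n = 2) in the EZH2 mutant, 65.2 ± 0.606 (n = 3) in the KMT2D mutant and 86.9 ± 4.92 (n = 3) in the double mutant. KMT2D, on the minus strand of chromosome 12 from 49018975 to 49059774 (ENSG00000167548.15), was at 27.2, 44.2 and 29.1 CPM in the wild-type libraries, 41.1, 40.9 and 34.5 in the KMT2D mutant, 19.5 and 41.2 in the EZH2 mutant and 65.6, 39.3 and 33.7 in the double mutant. Neither gene passed the test against wild type in any mutant line. KMT2D was at log2 0.19 (SE 0.27) in the KMT2D mutant and 0.46 (SE 0.27) in the double mutant, and EZH2 at -0.23 (SE 0.17) in the EZH2 mutant. Leaving out 1 library moved these values to between 0.069 (without wild type replicate 1) and 0.45 (without wild type replicate 2), between 0.098 (without double mutant replicate 1) and 0.70 (without wild type replicate 2), and between -0.51 (without EZH2 mutant replicate 2) and -0.021 (without EZH2 mutant replicate 1). Counts of 3′ ends show neither a point mutation nor a lesion elsewhere in the gene, so these levels check none of the genotype labels.

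The comparison of the EZH2 mutant with wild type asks what the gain-of-function mutation changes in this lymphoma line. HSPA8, a constitutive chaperone, rose from 81.6 ± 28.4 normalised CPM (SD, n = 3) to 909.7 ± 481 (n = 2), and GPER1, a membrane receptor for estrogen, rose by log2 2.12 (SE 0.14) and was chosen after its values were seen. FCGR2B, the inhibitory Fc receptor, rose at log2 2.53 (SE 0.34) and FCER2, the low-affinity IgE receptor CD23, at log2 2.29 (SE 0.28). IGLL5, an immunoglobulin lambda-like gene, fell from 792 ± 93.0 (n = 3) to 51.8 ± 10.8 (n = 2), at log2 -3.96 (SE 0.22). ACSS2, which makes acetyl-CoA from acetate, fell at log2 -4.15 (SE 0.55), and the smooth muscle myosin gene MYH11 at log2 -3.39 (SE 0.50). The phospholipase C gene PLCH2 (8.02-fold), the glutamate receptor gene GRIK3 (log2 2.42) and the actin-capping gene CAPG (log2 2.20) also rose, and the ankyrin-repeat gene ANKS6 (log2 -3.19) and PRKAR2B, a regulatory subunit of protein kinase A (log2 -3.20), fell. HSPA8 shares sequence with processed pseudogenes and IGLL5 with the immunoglobulin lambda constant genes, so their counts are uncertain. So are those of the small nucleolar RNA SNORA50C (log2 2.55) and the antisense gene FAM167A-AS1 (log2 -4.01).

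Camera called 5 lists in the EZH2 mutant, 2 of them also with an estimated correlation. Of 34 tested genes of MYC targets and ribosome biogenesis, 26 rose, 0 fell and 8 did not pass, with 27 up and 1 down when adjusted over the list alone. They included MYBBP1A (log2 1.74), the spermidine synthase SRM (log2 1.47) and the ribosomal RNA processing genes RRP12 (log2 1.59) and NOP2 (log2 1.44). The list's camera test gave adjusted p = 4.7e-12, and 0.0041 with an estimated correlation. Of 41 genes of the G2 and M phases, 23 fell, 1 rose and 17 did not pass (27 down and 1 up adjusted over the list alone), among them the mitotic kinase CDK1 (log2 -1.47) and the motor genes KIF20A (log2 -1.49) and KIF11 (log2 -1.55). Camera gave adjusted p = 3.4e-07, and 0.0095 with an estimated correlation. Of 25 genes of the CD40 and NF-kB response, 10 fell and 1 rose (11 and 1 adjusted over the list alone), with LTB, a lymphotoxin subunit, at log2 -0.96, RELB at -0.77 and the NF-kB inhibitor gene TNFAIP3 at -1.37. The camera adjusted p of that list was 0.016, 0.12 with an estimated correlation and 0.167 without EZH2 mutant replicate 2. Nuclear genes of oxidative phosphorylation rose in 26 of 47 cases with 0 falling (26 and 0 adjusted over the list alone), led by ATP5MC1, an ATP synthase subunit, at log2 1.65 (camera adjusted p = 2.6e-05, and 0.16 with an estimated correlation). Of 73 cytosolic ribosomal protein genes, which have many pseudogenes, 22 rose and 5 fell (24 and 5 adjusted over the list alone; camera adjusted p = 0.0017, 0.45 with an estimated correlation and 0.168 without EZH2 mutant replicate 2).

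Camera did not call the following lists in the EZH2 mutant. Among 11 tested PRC2 subunit genes, 4 fell and 7 did not pass, both as tested over all genes and adjusted over the list alone. The falls were RBBP4 (log2 -0.89), EZH1 (log2 -0.52), SUZ12 (log2 -1.34) and RBBP7 (log2 -1.23), and of these RBBP4 alone kept its call in every alternative run. Of 19 PRC1 subunit genes, 6 fell and 3 rose (the same adjusted over the list alone), with PCGF5 at log2 -2.81 and CBX8 at log2 2.13. Of 29 germinal centre B-cell genes, 9 fell and 5 rose (9 and 6 adjusted over the list alone), and the falls included BCL6, the master repressor of the germinal centre program (log2 -1.55), and LRMP (log2 -2.04). Of 18 reported PRC2 targets, 2 rose and 5 fell (2 and 7 adjusted over the list alone), with the cell cycle inhibitor CDKN1A at log2 1.96 and BMP7 at log2 -3.22. Among 29 B-cell receptor signalling genes, 10 rose and 2 fell (11 and 2 adjusted over the list alone), including the phosphatase gene PTPN6 (log2 1.25). Of 25 cholesterol synthesis genes, 10 fell and 2 rose (the same adjusted over the list alone), with FDFT1 at log2 -1.56 and SCD at log2 -1.54. Of 14 histone genes, 4 fell and 1 rose (the same adjusted over the list alone), with H1-10 at log2 -1.38. The summed level of all listed histone genes in the table, tested or not, was 6180 ± 629 CPM of the library total (n = 2) against 13244.5 ± 743 (n = 3). It was also lower than in wild type in the KMT2D mutant, at 9531 ± 712, and in the double mutant, at 8306 ± 1124 (n = 3 each). Among 25 interferon response genes, 7 rose and 3 fell (the same adjusted over the list alone), with ISG15 at log2 1.16.

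In total 2846 of 8813 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05 between EZH2 mutant and wild type, 1511 higher and 1335 lower. At least 2-fold changes were 419 higher and 882 lower. Tested genes were split by mean CPM into 3 classes. The lowest (1.57 to 13.9 CPM) held 473 of the large falls and 113 of the large rises. The middle class held 313 and 130, and the highest (from 56.2 CPM) 96 and 176. At equal depth 10205 and 10763 genes had a count in the EZH2 mutant libraries, against 11038 to 11416 in wild type. Whether low counts account for the excess of large falls was not tested. The split of all called genes into higher and lower depended on the scaling. It was 1015 higher and 1762 lower with upper-quartile factors, which shift the median gene by -0.16. It was 1059 and 1449 with the GC and abundance trends of each library removed. Without EZH2 mutant replicate 1, 1779 genes passed. With both trends removed 15 oxidative phosphorylation genes rose and 3 fell, and 12 ribosomal protein genes rose and 8 fell.

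**Figure D2:**
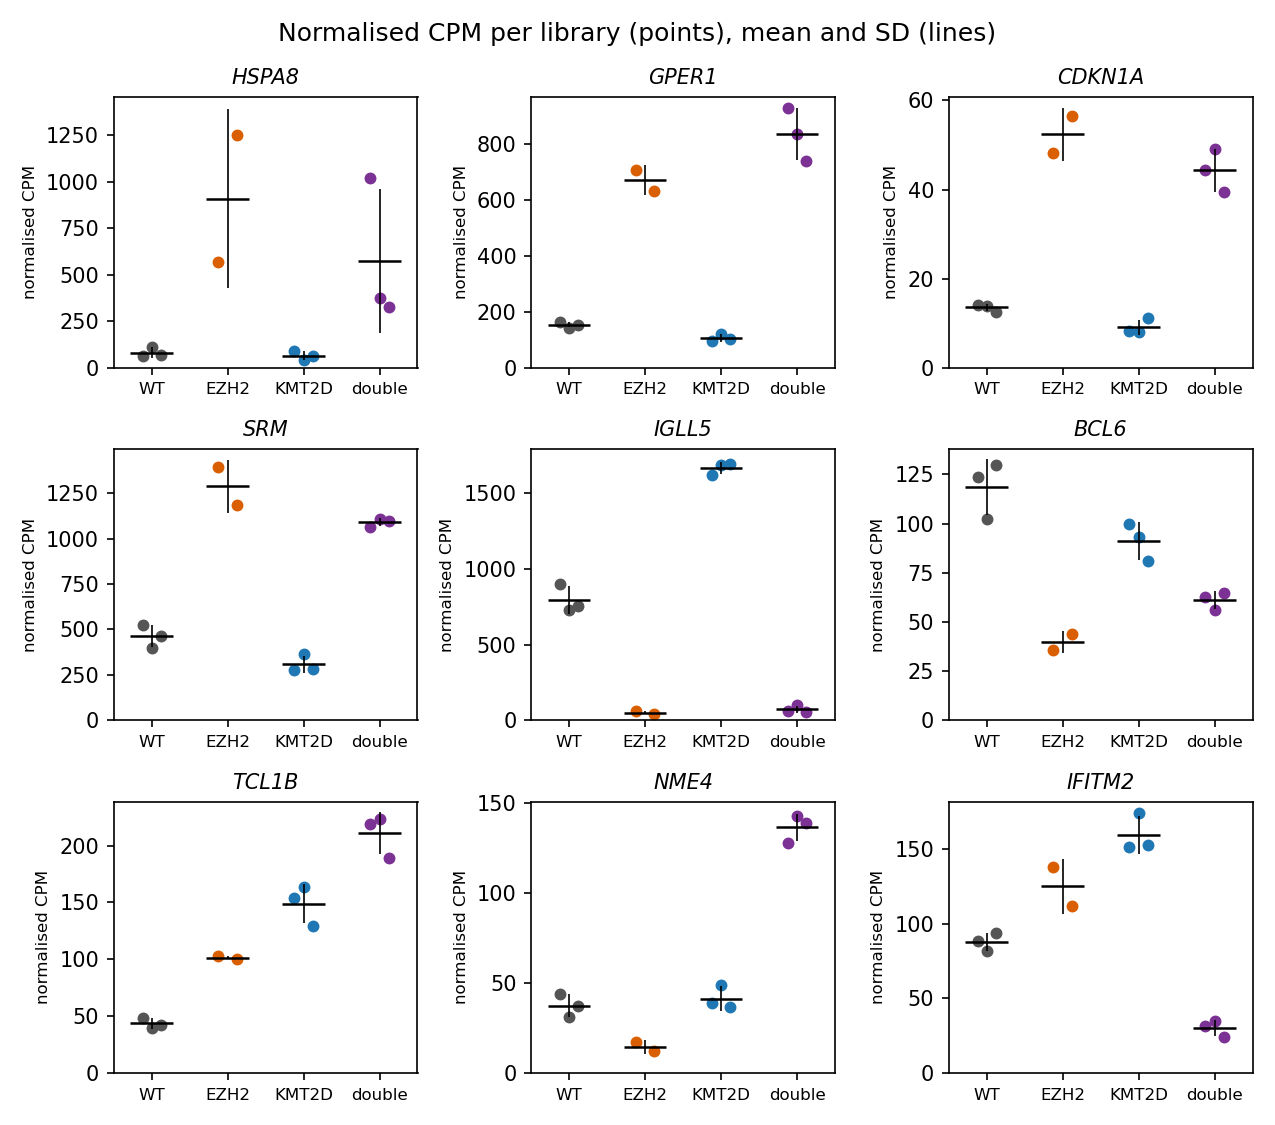
Normalised CPM of 9 genes in each library (points) with the mean (horizontal line) and SD (vertical line) of each line; the genes were chosen for display after their values were seen. HSPA8, GPER1, CDKN1A and SRM lie higher in every library with mutant EZH2 than in every wild-type and KMT2D mutant library, IGLL5 and BCL6 lie lower, and TCL1B, NME4 and IFITM2 differ between the double mutant and every other line.

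The comparison of the KMT2D mutant with wild type asks what loss of KMT2D changes. BIN1, a membrane-bending protein, rose from 5.66 ± 1.52 normalised CPM (SD, n = 3) to 42.4 ± 7.40 (n = 3), at log2 2.84 (SE 0.28). VPREB1, a part of the surrogate light chain of precursor B cells, rose from 5.73 ± 1.47 to 39.1 ± 5.98 (n = 3 each), at log2 2.80 (SE 0.28). TCL1B, of the AKT-activating TCL1 family, rose at log2 1.78 (SE 0.14), and LBH, DST and the actin-binding drebrin gene DBN1 rose at log2 2.37, 2.09 and 1.60. IGLL5, uncertain as above and chosen after its values were seen, rose at log2 1.07. The largest falls were CLEC11A, a secreted lectin-family growth factor, from 26.1 ± 0.908 to 4.36 ± 0.966 (n = 3 each), at log2 -2.61 (SE 0.29), and TEAD2, a transcription factor of the Hippo pathway, at log2 -2.06 (SE 0.29). The water and glycerol channel gene AQP3 fell at log2 -2.05 and the fatty acid amide hydrolase gene FAAH at log2 -1.89.

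CLEC11A and TEAD2 lie on the long arm of chromosome 19, where lower counts in the KMT2D mutant ran along most of the arm. The median log2 fold change of its 384 tested genes was -0.71, with 191 lower and 5 higher, while the medians of the other arms lay between -0.07 and 0.14. In order along the arm, 3 blocks of 25 genes had medians of 0.06, -0.08 and 0.23, and the following 12 blocks, from ZNF383 to the end of the arm, had medians between -0.97 and -0.58. Those 309 genes had a median of -0.81, which is 56.9% of the wild-type level, and 93.5% of them lay below 0. The arm held 4.36% of the tested genes and 48.4% of the genes called lower. Its median in the KMT2D mutant libraries was -0.68, -0.61 and -0.72 relative to the mean of the wild-type libraries. In double mutant against wild type it was 0.13.

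**Figure D3:**
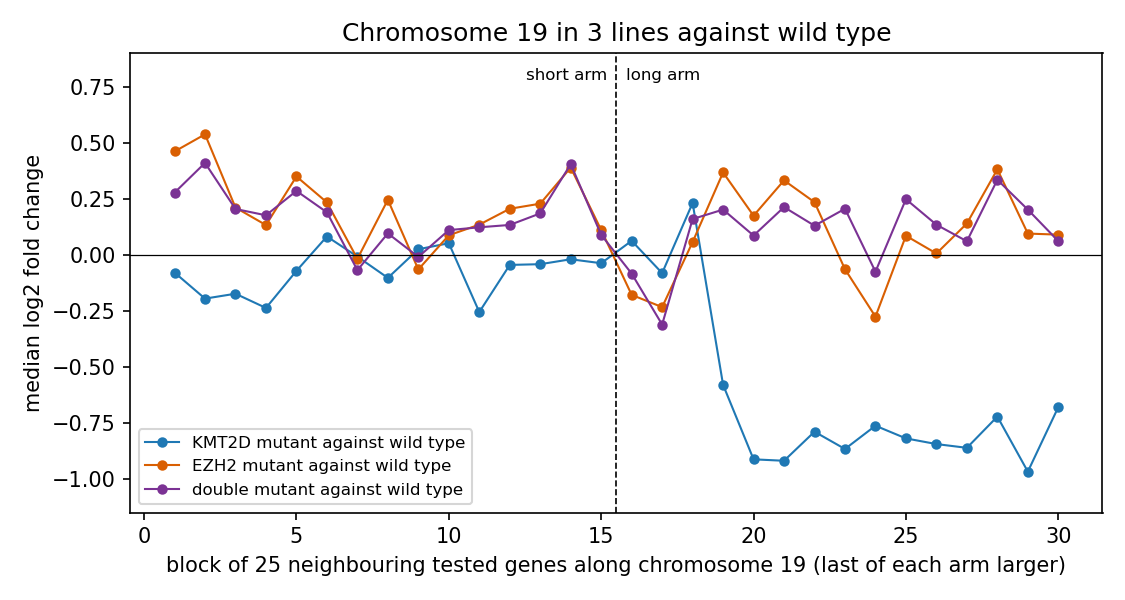
Median log2 fold change against wild type of blocks of neighbouring tested genes along chromosome 19, from the end of the short arm to the end of the long arm, with 25 genes per block except the last of each arm; lines are the 3 mutant lines. From block 4 of the long arm on, the KMT2D mutant lies between -0.97 and -0.58 while the other lines lie between -0.28 and 0.38.

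Of 20 genes of MHC class I presentation, 4 rose, 0 fell and 16 did not pass in the KMT2D mutant (6 and 0 adjusted over the list alone), namely HLA-E (log2 0.71), the class I activator NLRC5 (log2 0.60), HLA-F (log2 0.55) and the peptide transporter gene TAP1 (log2 0.43, a call lost in 7 alternatives). Class I genes share sequence with each other, so the counts of HLA-E and HLA-F are uncertain. The camera adjusted p of the list was 0.0026, and 0.28 with an estimated correlation. With the GC trend removed 7 of its genes rose, and with the GC and abundance trends removed 9. Of 34 genes of MYC targets and ribosome biogenesis, 6 fell and 0 rose (7 and 0 adjusted over the list alone), including the nucleolar fibrillarin gene FBL (log2 -0.82, on the long arm of chromosome 19) and the ornithine decarboxylase gene ODC1 (log2 -0.73). Camera gave adjusted p = 0.0026, and 0.18 with an estimated correlation. Of 36 S phase genes, 5 fell and 0 rose (9 and 0 adjusted over the list alone), with MCM4, a subunit of the replicative helicase, at log2 -0.53 (camera adjusted p = 0.010, 0.25 with an estimated correlation and 0.0673 without wild type replicate 3). With the GC trend removed 8 of them fell. Germinal centre genes went both ways, with 2 of 29 higher and 6 lower (3 and 8 adjusted over the list alone), with POU2F2, on the long arm of chromosome 19, at log2 -1.18. Among 18 genes reported as KMT2D targets in lymphoma, 1 rose, 2 fell and 15 did not pass (1 and 3 adjusted over the list alone), with BTG2 at log2 0.69, S1PR2 at log2 -0.72 and DUSP2 at log2 -0.50, a call lost in 6 alternatives. The list median was -0.04. Of 18 KMT2 complex genes, 2 fell and 0 rose (3 and 0 adjusted over the list alone). Of the 73 cytosolic ribosomal protein genes, 7 fell and 0 rose (7 and 0 adjusted over the list alone), among them RPS19 (log2 -1.04) and RPS16 (log2 -0.52), both on the long arm of chromosome 19.

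Between KMT2D mutant and wild type, 675 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 280 higher and 395 lower, with 139 higher and 114 lower by at least 2-fold. With the long arm of chromosome 19 left out, 401 passed, 213 higher and 188 lower, and with the GC and abundance trends removed the split was 460 higher and 415 lower. The count was 446 without wild type replicate 1, 347 without KMT2D mutant replicate 1 and 339 without KMT2D mutant replicate 3.

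**Figure D4:**
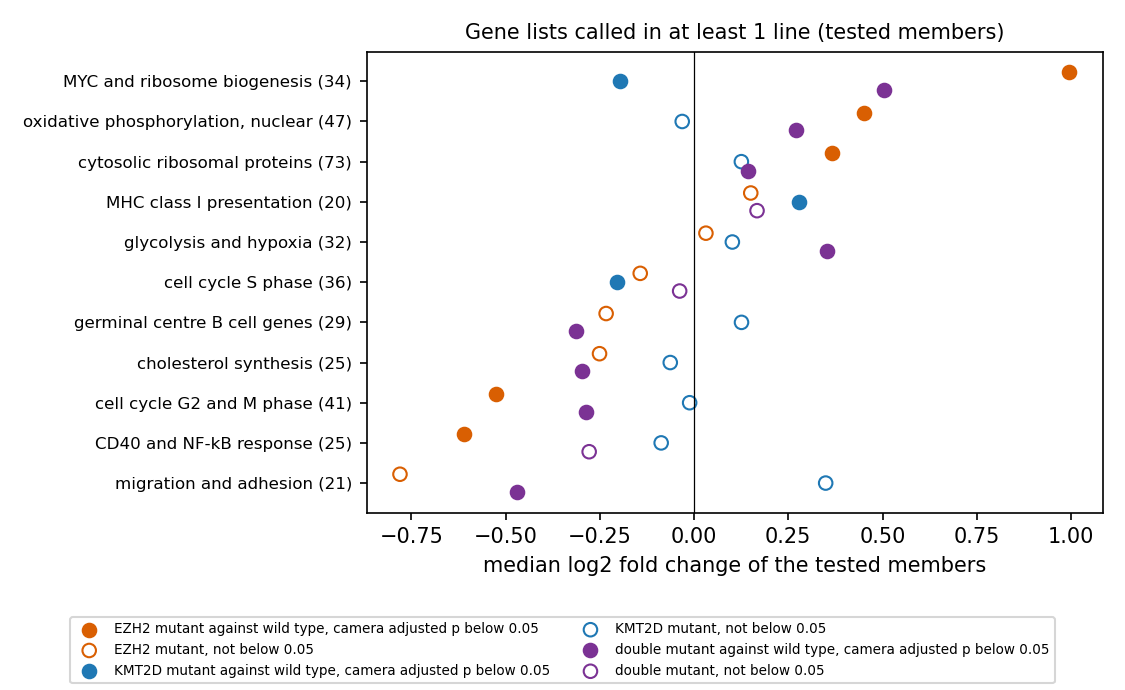
Median log2 fold change against wild type of the tested members of each gene list that camera called in at least 1 mutant line, with the number of tested members in brackets; filled points have a camera adjusted p below 0.05 and open points do not. The MYC and ribosome biogenesis list lies at 0.99 in the EZH2 mutant, 0.50 in the double mutant and -0.20 in the KMT2D mutant.

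The double mutant against wild type shows both changes together. GPER1 rose from 154 ± 9.22 normalised CPM (SD, n = 3) to 836 ± 93.1 (n = 3), at log2 2.44 (SE 0.13). TCL1B rose from 43.6 ± 4.69 to 211 ± 18.5 (n = 3 each), at log2 2.28 (SE 0.15), and DDIT4, a stress-induced inhibitor of mTOR signalling, rose at log2 2.09 (SE 0.14). ANXA2, a membrane-binding annexin, fell from 40.7 ± 6.44 to 1.31 ± 0.895 (n = 3 each), at log2 -5.04 (SE 0.39). PREX1, a Rac activator, fell at log2 -4.19 (SE 0.27), ACSS2 at log2 -4.08 (SE 0.44), and the cytidine deaminase gene APOBEC3C, whose counts are uncertain because it has paralogs, at log2 -3.84 (SE 0.25). The bicarbonate transporter family gene SLC4A11, with 3 counts against 79, was 18.3-fold lower (95% interval 6.02 to 90.4). HSPA8, uncertain as above, rose at log2 2.81 (SE 0.59), with adjusted p = 0.013 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and 0.0579 without wild type replicate 3. NME4, a mitochondrial nucleoside diphosphate kinase, rose at log2 1.88 (SE 0.17).

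Of 34 genes of MYC targets and ribosome biogenesis, 16 rose, 0 fell and 18 did not pass in the double mutant (20 and 0 adjusted over the list alone), with SRM at log2 1.24 and MYBBP1A at log2 1.04. Camera gave adjusted p = 3.9e-08, and 0.014 with an estimated correlation. Glycolysis and hypoxia genes rose in 14 of 32 cases and fell in 2 (15 and 2 adjusted over the list alone), with PFKFB4, a regulator of glycolytic flux, at log2 1.33, the glucose transporter gene SLC2A1 at log2 0.94 and the hexokinase gene HK1 at log2 -1.67 (camera adjusted p = 7.6e-04, and 0.037 with an estimated correlation). Of 25 cholesterol synthesis genes, 8 fell and 0 rose (8 and 0 adjusted over the list alone), with INSIG1 at log2 -1.37, FDFT1 at log2 -1.04 and ACAT2 at log2 -0.93 (camera adjusted p = 0.0013, and 0.037 with an estimated correlation). Of 29 germinal centre genes, 10 fell and 1 rose (12 and 1 adjusted over the list alone), with ASB13 at log2 -1.58 and BCL6 at log2 -0.95 (camera adjusted p = 0.0031, and 0.037 with an estimated correlation). Of 41 genes of the G2 and M phases, 6 fell and 0 rose (6 and 0 adjusted over the list alone), with CDK1 at log2 -1.04 (camera adjusted p = 0.0014, and 0.037 with an estimated correlation). Of 47 oxidative phosphorylation genes, 15 rose and 0 fell (16 and 0 adjusted over the list alone), with ATP5MC1 at log2 1.28 (camera adjusted p = 1.2e-04, and 0.13 with an estimated correlation). Of 21 migration and adhesion genes, 6 fell and 0 rose (6 and 0 adjusted over the list alone), with the integrin gene ITGB2 at log2 -3.15. The camera adjusted p of that list was 0.037, 0.14 with an estimated correlation, 0.0765 without wild type replicate 1 and 0.0518 without double mutant replicate 3. Cytosolic ribosomal protein genes rose in 5 of 73 cases and fell in 2 (4 and 2 adjusted over the list alone), with a camera adjusted p of 0.045, 0.51 with an estimated correlation and 0.0503 with the replicate block. Of 25 interferon response genes, 6 rose and 1 fell (6 and 1 adjusted over the list alone), with the antiviral gene MX1 at log2 1.58 and IFITM2 at log2 -1.55. Camera did not call that list.

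Between double mutant and wild type, 2087 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1068 higher and 1019 lower. At least 2-fold changes were 152 higher and 614 lower. At equal depth 10463 to 10721 genes had a count in the double mutant libraries, against 11038 to 11416 in wild type. Whether low counts account for the excess of large falls was not tested here either. The split of all called genes was 728 higher and 1318 lower with upper-quartile factors, which shift the median gene by -0.11. It was 927 and 1332 without a filter on low counts. Without double mutant replicate 1 the count was 1381, and with the GC and abundance trends removed 17 genes of the G2 and M phases and 13 cholesterol synthesis genes fell, and 9 oxidative phosphorylation genes rose. In that run 8 ribosomal protein genes rose and 4 fell, and with upper-quartile factors 4 rose and 4 fell.

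Double mutant against EZH2 mutant asks what loss of KMT2D adds when EZH2 is mutant. NME4 rose from 14.7 ± 3.89 normalised CPM (SD, n = 2) to 136 ± 7.75 (n = 3), at log2 3.28 (SE 0.24). The glutathione transferase gene GSTO1 rose at log2 2.38 (SE 0.26) and the LIM-domain gene CSRP1 at log2 2.21 (SE 0.29). PDIA5, a protein disulfide isomerase, fell at log2 -3.73 (SE 0.57), and DBN1 at log2 -3.56 (SE 0.38). PREX1 fell from 45.4 ± 5.28 (n = 2) to 4.03 ± 2.03 (n = 3), at log2 -3.55 (SE 0.31). RIPOR2, an inhibitor of RhoA, fell at log2 -2.77 (SE 0.25), and the inhibitory receptor gene CD300A at log2 -2.76 (SE 0.34). Of 34 genes of MYC targets and ribosome biogenesis, 4 fell and 1 rose (14 and 1 adjusted over the list alone), with NOP56 at log2 -0.78 and RRP12 at log2 -0.81. Camera gave adjusted p = 4.4e-08, and 0.013 with an estimated correlation. The G2 and M phase list had 1 of 41 genes higher and 0 lower (1 and 0 adjusted over the list alone) with a median of 0.33, KIF20A at log2 0.92, and a camera adjusted p of 2.5e-06 (0.013 with an estimated correlation). Of 32 glycolysis and hypoxia genes, 3 rose and 1 fell (6 and 2 adjusted over the list alone), with BNIP3 at log2 0.69 and HK1 at log2 -1.90 (camera adjusted p = 9.3e-05, and 0.023 with an estimated correlation). Among 29 B-cell receptor signalling genes, 3 fell and 0 rose (5 and 0 adjusted over the list alone), with FCGR2B at log2 -2.00 and CD79B, a subunit of the receptor, at log2 -0.67 (camera adjusted p = 0.013, 0.18 with an estimated correlation and 0.0925 without EZH2 mutant replicate 2). Oxidative phosphorylation genes (2 of 47 lower and 0 higher, 7 and 1 adjusted over the list alone) and cytosolic ribosomal protein genes (2 of 73 lower and 0 higher, 3 and 0 adjusted over the list alone) had camera adjusted p of 0.039 and 0.013, which were 0.42 and 0.59 with an estimated correlation and 0.624 and 0.836 without EZH2 mutant replicate 2. With the replicate block, the p of the oxidative phosphorylation list was 0.0753. IFITM2 fell at log2 -2.05, and the reported KMT2D targets DUSP2 and CCR6 fell at log2 -0.85 and -2.70, 2 of 18 on that list (3 adjusted over the list alone).

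Between double mutant and EZH2 mutant, 202 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 63 higher and 139 lower, with 39 higher and 71 lower by at least 2-fold. The split was 88 and 116 with upper-quartile factors and 179 and 159 with the GC and abundance trends removed. The count was 381 without a filter, 92 with only these groups fitted, 102 without EZH2 mutant replicate 1 and 99 without double mutant replicate 3. Of the genes named here, NOP56, RRP12, KIF20A, BNIP3, CD79B, DUSP2 and CCR6 lost their calls in at least 1 alternative. With the GC trend removed 8 genes of MYC targets and ribosome biogenesis and 4 of oxidative phosphorylation fell, and 6 of glycolysis and hypoxia rose. With the GC and abundance trends removed 5 genes of the G2 and M phases rose and 0 ribosomal protein genes fell.

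Double mutant against KMT2D mutant asks what mutant EZH2 adds when KMT2D is lost. GPER1 rose from 108 ± 13.5 normalised CPM (SD, n = 3) to 836 ± 93.1 (n = 3), at log2 2.96 (SE 0.14). CEND1, a regulator of neuronal cell cycle exit, rose at log2 2.45 (SE 0.19) and CDKN1A at log2 2.26 (SE 0.21). BIN1 fell from 42.4 ± 7.40 to 1.72 ± 1.13 (n = 3 each), at log2 -4.67 (SE 0.38). The milk fat globule protein gene MFGE8 fell at log2 -4.63 (SE 0.42) and the proton channel gene HVCN1 at log2 -4.57 (SE 0.29). VPREB1, with 3 counts against 299, was 68.4-fold lower (95% interval 23.2 to 334), and IGLL5, uncertain as above, fell at log2 -4.52 (SE 0.19). CD3EAP (log2 2.79), NLRP4 (log2 2.51) and HSPBP1 (log2 2.35) rose and lie on the long arm of chromosome 19, whose median here was 0.81 with 227 genes higher.

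Of 34 genes of MYC targets and ribosome biogenesis, 23 rose and 0 fell in double mutant against KMT2D mutant (25 and 1 adjusted over the list alone), with SRM at log2 1.83, BOP1 at log2 1.53 and ODC1 at log2 1.34 (camera adjusted p = 8.5e-09, and 0.011 with an estimated correlation). Of 47 oxidative phosphorylation genes, 19 rose and 3 fell (19 and 3 adjusted over the list alone), with ATP5MC1 at log2 1.65 (camera adjusted p = 7.8e-04, and 0.21 with an estimated correlation). Of 21 migration and adhesion genes, 9 fell and 2 rose (9 and 2 adjusted over the list alone), with ITGB2 at log2 -3.72, the follicle-homing receptor gene CXCR5 at log2 -1.76 and RHOH at log2 -1.36 (camera adjusted p = 0.020, and 0.21 with an estimated correlation). Camera called no other list in this comparison, in which 41.9% of all tested genes were called. Of 29 germinal centre genes, 13 fell and 6 rose (15 and 6 adjusted over the list alone), with ASB13 at log2 -1.89 and POU2F2, on the long arm of chromosome 19, at log2 1.35. Of 18 reported PRC2 targets, 10 fell and 2 rose (10 and 2 adjusted over the list alone), with NLRC5 at log2 -0.84 and CD40 at log2 -0.58. EBF4, with 0 counts against 51, was at least 11.7-fold lower, taking 3 counts over the group as the floor. In the interferon response list, 6 of 25 genes rose and 2 fell (6 and 2 adjusted over the list alone), with MX1 at log2 2.10 and IFITM2 at log2 -2.41. EZH2 itself was at log2 0.42 (SE 0.15), with adjusted p = 0.0300 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, a call that 11 of the alternatives ended, with adjusted p from 0.0574 to 0.164.

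Between double mutant and KMT2D mutant, 3695 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1864 higher and 1831 lower, with 495 higher and 1123 lower by at least 2-fold. Of the 3 classes by mean CPM, the lowest held 748 of the large falls and 137 of the large rises. The middle class held 292 and 162, and the highest 83 and 196. At equal depth 10463 to 10721 genes had a count in the double mutant libraries, against 11385 to 11569 in the KMT2D mutant. Whether low counts account for the excess of large falls was not tested in this comparison. With upper-quartile factors, which shift the median gene by -0.15, the split was 1342 higher and 2300 lower, and with the GC and abundance trends removed 8 oxidative phosphorylation genes rose and 4 fell, and of the migration and adhesion genes 0 rose and 12 fell.

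The 4 lines form a design in which the effect of mutant EZH2 can be compared with and without KMT2D. That comparison too rests on 1 line per genotype. The interaction was 3.14 (SE 0.30) on the log2 scale for NME4, which fell in the EZH2 mutant (log2 -1.40) and rose in double mutant against KMT2D mutant (log2 1.74). It was -5.16 (SE 0.47) for DBN1, -4.42 (SE 0.45) for the glucosidase gene PGGHG and -5.34 (SE 0.60) for BIN1, which stood at 12.3 and 7.45 CPM in the EZH2 mutant libraries and at 0.99, 3.02 and 1.16 in the double mutant. IFITM2 had an interaction of -2.91 and MX1 one of 1.27. Of 20 MHC class I genes, 2 had a lower and 0 a higher EZH2 effect without KMT2D (5 and 0 adjusted over the list alone), TAPBPL at -1.06 and NLRC5 at -0.71, with a list median of -0.32 (camera adjusted p = 0.0023, and 0.28 with an estimated correlation). The G2 and M phase list had 0 of 41 genes past the threshold either way (0 adjusted over the list alone), a median interaction of 0.42 and a camera adjusted p of 3.4e-05 (0.034 with an estimated correlation). In the S phase list 1 of 36 genes, UNG at 1.14, had a higher and 0 a lower EZH2 effect (1 and 0 adjusted over the list alone; camera adjusted p = 0.023, 0.28 with an estimated correlation and 0.207 without EZH2 mutant replicate 1). In the ribosomal protein list 1 of 73, RPL38 at -1.04, had a lower and 0 a higher one (4 and 0 adjusted over the list alone; camera adjusted p = 0.0090, 0.50 with an estimated correlation and 0.269 without EZH2 mutant replicate 2).

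The interaction passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment for 266 genes, 132 higher and 134 lower, and 76 of the 132 lie on the long arm of chromosome 19. Without that arm 144 genes passed, 50 higher and 94 lower, and without a filter on low counts 482 passed, 294 and 188. Without single replicates the count fell to 147 (EZH2 mutant 2), 153 (KMT2D mutant 1) and 159 (KMT2D mutant 3). Of the genes named here, MX1 lost its call at equal depth, and TAPBPL, NLRC5, UNG and RPL38 in 5 or more alternatives each. With the GC trend removed 6 genes of the G2 and M phases had a higher EZH2 effect, and with the GC and abundance trends removed 5. For the ribosomal protein list these runs gave 2 higher and 2 lower, and 4 higher and 2 lower.

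Across genes, the EZH2 effect in wild-type cells and in cells without KMT2D, which share no library, had a Pearson correlation of 0.649 and a Spearman correlation of 0.701 (jackknife SD of the Pearson value over libraries 0.116), where genes are not independent replicates. Of the 2846 genes called in the first, 92.7% had the same direction in the second, and the slope was 0.661. Both comparisons called 1081 genes higher, against 320 for independent lists, and 820 lower, against 277. They also had trends in the same direction on GC content (Spearman 0.354 and 0.383) and abundance (0.369 and 0.385). With the GC trend removed the Pearson correlation was 0.619. It was not computed with the abundance trend removed, so what part of the agreement the trends make was not settled. For loss of KMT2D the correlation between backgrounds was 0.0993 (Spearman 0.133), with a jackknife SD over libraries of 0.146, and ran from 0.0253 without EZH2 mutant replicate 1 to 0.207 without EZH2 mutant replicate 2. It was 0.0559 over genes of at least 10 CPM and 0.0592 with the GC trend removed. Of the 675 genes called in the wild-type background, 58.2% had the same direction in the EZH2 mutant background. Outside the long arm of chromosome 19 that share was 59.5% of 479 genes. Both comparisons called 50 genes, of which 29 had the same direction and the rest went in opposite directions. The 29 were 6 higher and 23 lower, against 2.00 and 6.23 for independent lists. No such expectation was computed for the genes in opposite directions. These values therefore do not show that agreement in direction exceeds disagreement.

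**Figure D5:**
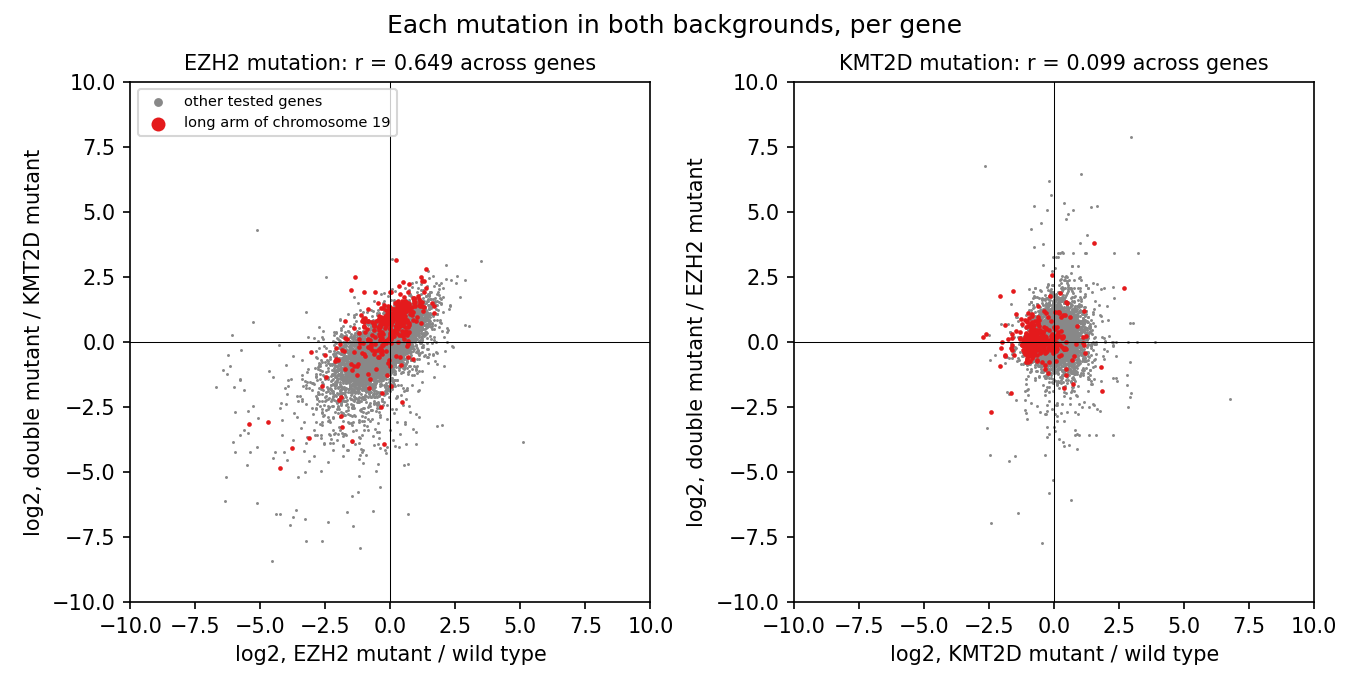
Log2 fold change of each tested gene (points) for the EZH2 mutation (left panel) and the KMT2D mutation (right panel), in the wild-type background on the horizontal axis and in the background of the other mutation on the vertical axis; red points lie on the long arm of chromosome 19. The EZH2 effects follow each other across backgrounds (r = 0.649), and the KMT2D effects hardly do (r = 0.0993).

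The effects of the single mutations, both measured against the same wild-type libraries, had a correlation of -0.163 across genes (Spearman -0.211), with a jackknife SD over libraries of 0.118. It ran from -0.218 without EZH2 mutant replicate 2 to -0.0812 without EZH2 mutant replicate 1, and was -0.101 with the GC trend removed. The EZH2 mutant and the KMT2D mutant against wild type had opposite trends on GC content (Spearman 0.354 and -0.303) and abundance (0.369 and -0.242). What part of the correlation these trends make was not tested beyond that run. Simulated unchanged groups that shared simulated wild-type libraries gave 0.392 (0.370 to 0.411 in 20 simulations). Genes were drawn independently there, without the GC and abundance trends of the real libraries. That range is therefore no full null for the observed correlation. The covariance was -0.0755 against 0.0417 in the simulations, a difference of -0.117. Of the 279 genes called in both single mutants, 96 had the same direction and the rest went in opposite directions. In both lines 30 genes were higher, against 48.0 for independent lists, and 66 lower, against 59.8. The simulations gave 0 and 0, but they called a mean of 0.1 genes in the EZH2 mutant and 0 in the KMT2D mutant. They therefore set no expectation for this overlap. Outside the long arm of chromosome 19, 30 genes were higher in both lines, against 46.9, and 43 lower, against 31.1. The 3 wild-type libraries were not split between the 2 comparisons, so the part of the overlap owed to the shared controls was not measured that way. TCL1B rose in both single mutants, while IGLL5, GPER1 and SRM went in opposite directions in them.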

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

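Of the tests in this part, the one of KMT2D loss acting in any background, the one with held-out pairs of libraries and the jackknife over libraries were chosen only after the result was seen, as were the runs with the GC trend removed and at equal depth. The interaction passed edgeR's test for 266 genes, which is what brought the following results here. Of the 132 higher ones, 76 lie on the long arm of chromosome 19, as does CLEC11A below, and without that arm 144 genes passed. The arm had a median interaction of 0.70 and a median of -0.71 in the KMT2D mutant against wild type. Its calls therefore need not be effects of mutant EZH2. The log2 interactions named by the rule were ANKS6 3.39, FAM167A-AS1 3.14, NME4 3.14, CLEC11A 2.90 and AQP3 2.74 upward. Downward they were BIN1 -5.34, DBN1 -5.16, VPREB1 -4.46, PGGHG -4.42 and SLC4A11 -4.41. VPREB1 and SLC4A11 had 3 counts each over the double mutant libraries, so their fitted values are imprecise and their place in this order is uncertain. FAM167A-AS1 was no longer called without EZH2 mutant replicate 2 (adjusted p = 0.116 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and VPREB1 neither without it nor at equal depth. By camera, the lists with a different EZH2 effect were MHC class I presentation (median -0.32), S phase (0.24), the G2 and M phases (0.42) and cytosolic ribosomal proteins (-0.26), and with an estimated correlation camera called the G2 and M phase list alone. No line had 4 libraries, so no library was tested as an outlier.

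The KMT2D mutant had lower counts along the long arm of chromosome 19 from block 4 of 25 genes on. A GC trend as the cause is argued against by the median of -0.64 left on the arm after that trend was removed. Loss of KMT2D lowering these genes in any background is argued against by the median of -0.022 between double mutant and EZH2 mutant. A candidate explanation is a single change of dose in this line, since the distal genes shifted alike at every level, with medians from -0.74 to -0.83 over 3 classes of genes by mean CPM. DNA copy number was not measured here, so that stays a hypothesis.

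Few genes changed between double mutant and EZH2 mutant. Inflated fold changes of the called genes as the whole cause are argued against by slopes of 0.452 to 0.774 in 9 held-out pairs of libraries, a test picked after the slope below and an earlier simulation had been seen. Low power from 2 EZH2 mutant libraries as the whole cause was taken to need a slope of at least 0.5 of that fold change on the one between KMT2D mutant and wild type, outside the long arm of chromosome 19. The slope was 0.122 (0.0811 without double mutant replicate 1 to 0.228 without EZH2 mutant replicate 2). By its SE over genes, 0.0384, the slope met the bound of 0.25 written beforehand, but genes are not independent. By a jackknife SD over libraries of 0.121 it did not, 2 SD above it being 0.364. That value lies below 0.5, but this reading was chosen after these values were seen, and a held-out pair of the same lines gave 0.452. The slope therefore does not exclude low power, and low power together with inflated fold changes was not tested. A different effect of KMT2D loss in the 2 backgrounds may remain, as may a part for low power and differences between lines that arose apart from the mutations, which 1 line per genotype cannot separate.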

How the results depend on the processing

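The runs with the GC trend removed, with the GC and abundance trends removed, without the long arm of chromosome 19 and at equal depth were chosen only after the data were seen. Genes changed between KMT2D mutant and wild type numbered 401 without the arm and 439 at equal depth, against 675. Between double mutant and EZH2 mutant they numbered 381 with no filter, 92 with only the groups compared, 316 with the GC trend removed and 338 with both trends removed, against 202. For the interaction they numbered 482 with no filter, 443 with the GC trend removed, 469 with both removed, 144 without the arm and 167 at equal depth, against 266. Of the 675 genes, 479 lie outside the arm, so the arm's own calls do not account for the whole drop to 401. Beyond those calls the cause was not tested.

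Leaving out 1 library at a time gave 1779 to 2874 genes for EZH2 mutant against wild type, 339 to 669 for KMT2D mutant against wild type, 1381 to 2052 for double mutant against wild type, 99 to 242 for double mutant against EZH2 mutant, 2708 to 3370 for double mutant against KMT2D mutant and 147 to 309 for the interaction. Without 1 EZH2 mutant library the other is assumed to vary like the other groups. The correlation of the EZH2 effect between backgrounds was 0.541 to 0.668, that of the KMT2D effect 0.0253 to 0.207, and that of the single mutants -0.218 to -0.0812. KMT2D, which passed no test, turned direction in the EZH2 mutant against wild type (0.14 without wild type replicate 2, range -0.81 to 0.30, the highest without EZH2 mutant replicate 1), in double mutant against KMT2D mutant (-0.10 to 0.43, the lowest without double mutant replicate 1) and in the interaction (-0.0076 to 1.09, the lowest without EZH2 mutant replicate 1).

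A replicate block gave 2445, 629, 2002, 151, 3630 and 230 genes in the order above, and ended 2 list calls. Same-number libraries had deviations from their line's mean correlated at -0.289 to 0.376 over 15 pairs. The deviations of the 2 EZH2 mutant libraries mirror each other, so pairs with them say little. Between KMT2D mutant and double mutant, same-number pairs were at 0.287, 0.206 and 0.066, and other pairs from -0.239 to -0.0029. A factor shared by same-number libraries of these lines is therefore not excluded. Of 10022 alternative values of 561 calls of named genes, 9155 stayed past the threshold in the same direction, 867 did not pass and 0 turned direction, and 370 calls held in every alternative run. Only the groups compared was not run for the interaction.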

Other observations

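Of the tests in this part, the removal of GC and abundance trends together, the shared preparation batch and the run at equal depth were chosen only after the result was seen. IFITM2 and MX1, both antiviral interferon-response genes, moved apart in the double mutant, where IFITM2 fell (log2 -1.55) and MX1 rose (log2 1.58) against wild type. TCL1B rose against wild type in each mutant line, at log2 1.23 in the EZH2 mutant, 1.78 in the KMT2D mutant and 2.28 in the double mutant.

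The EZH2 mutant differed from wild type at many genes, with a trend on GC content and abundance (Spearman 0.354 and 0.369). These trends as the whole cause are argued against by the 2508 genes called after both were removed, 1449 of them lower, and a difference in depth by the 2307 called at equal depth. Of those 2508 genes, 1929 were among the 2846 called in the main run, so removing the trends changed which genes were called. An earlier test on 3 classes of abundance, with 26.2% of the calls in the most abundant class lower against a bound of 25%, decided nothing, and it and the run with the GC trend alone removed (2720 genes) had been seen before the combined one was chosen. The labels name no preparation batch, and one shared by EZH2 mutant and double mutant cannot be told apart from the mutation, because the correlation of 0.649 between backgrounds would arise either way and so decides nothing.

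Other splits of the 6 libraries were counted for the comparisons with 3 libraries per line. The real split was the 1 of 10 with as many genes for KMT2D mutant against wild type (675, highest other 0), for double mutant against wild type (2087, highest other 0) and for double mutant against KMT2D mutant (3695, highest other 0). With 10 splits the share cannot be under 0.1.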
